A study of Mus musculus with 16 samples.

How the data were processed

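Total RNA from the hippocampus of C57BL/6 wild-type mice was profiled by RNA sequencing in 16 libraries, 4 from each of 4 groups: vehicle or beta-sitosterol (100 mg/kg, intraperitoneal), with tissue taken 1 h or 6 h after the injection. Per the labels, each library is a different animal, RNA with an integrity number of at least 7 was used, and the libraries were prepared with the TruSeq mRNA kit. The p-values below therefore measure the spread between mice, except those of camera, which ranks a list against other genes. Groups and animal numbers were taken from the labels.

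The deposited table of raw counts gives whole numbers of reads per Ensembl gene, made by the authors before any normalization. Per the submitters' processing notes, the tools were CASAVA 1.8.2, cutadapt, TopHat2 2.0.10, HTSeq 0.6.1p1 and DESeq2 1.6.3, with the genome build GRCm38; the notes do not tie a step to a tool. The strand setting of the counting and the annotation release are not given in the sources used here. Without the strand setting, reads of overlapping genes on opposite strands cannot be told apart. Of 64 named genes, 16 have exons overlapping another gene on the opposite strand and 5 on the same strand, and these carry that uncertainty. A second deposited table holds a normalized signal, the authors' counts multiplied by a factor per library between 0.853 and 1.11. Those factors differ by at most 0.000562% from the reciprocals of size factors computed here with DESeq2.

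All tests of the main results used the raw counts. The table holds 46603 gene IDs, of which 46005 were matched to a symbol and 598 were not. Low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 17055 genes with 99.9% of the reads. The libraries hold 24815581 to 31266644 counted reads. The relative spread between mice, the biological coefficient of variation, was 0.0988 as a common value over genes. Precision for a gene with many reads is thus set by the mice and not by counting error.

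Differential expression was tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, a robust quasi-likelihood fit (glmQLFit and glmQLFTest) to all 16 libraries with a mean per group and 12 residual degrees of freedom, and no covariate. The 6 comparisons were beta-sitosterol against vehicle at 1 h, at 6 h and averaged over both times, the difference of the effects at 6 h and 1 h, and 6 h against 1 h within vehicle and within beta-sitosterol mice. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. CPM are the counts scaled to library size with TMM, and log-CPM used a prior count of 2.

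The lists number 26, 13 of functional groups and 13 of cell type or tissue markers, with 450 members, of which 428 were tested and 1 was matched through an older symbol. Each list was tested with camera from limma 3.58.1 on log-CPM with an inter-gene correlation of 0.01, adjusted over the 26 lists of a comparison. The same lists were tested with an estimated correlation, with fry, and by exact permutation of the list score, the mean log-CPM of the members. With 4 mice against 4 there are 70 arrangements, which allow no two-sided p under 0.0286. A count of members "adjusted over the list alone" applies the Benjamini-Hochberg adjustment to the members of that list and is given beside the count over all genes.

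The genes named in the text follow a rule. Of the called genes of a comparison, up to 10 per direction with the largest changes are named. Where fewer than 5 were called, the 5 with the smallest p in each direction are given as values that did not pass. Fos, Egr1, Arc, Npas4, Fkbp5, Sgk1, Tsc22d3, Per1, Abca1 and Ttr are reported whatever their result. Sgk1, Tsc22d3 and Per1 had log2 fold changes of 0.22, 0.089 and -0.11 at 1 h and -0.0013, 0.041 and -0.062 at 6 h. Some further genes are not reported here. Members of lists that were called only over the list alone fall outside this rule, as do Ppp1r16a and Llgl1 over both times, and were chosen after their values were seen. The grouping, tests, lists, naming rule and first set of alternatives were fixed before the data were examined.

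That first set of alternatives was RLE scaling, no low-count filter, a strict filter at a mean of 5 CPM, a DESeq2 1.42.0 Wald test, limma-trend on the deposited normalized signal plus 1, a fit to only the groups compared, the choroid plexus score as a covariate, and leaving out each mouse in turn. Chosen after seeing the data were a per-library correction of log-CPM for transcript GC content and length (splines with 5 degrees of freedom, MASS), that correction together with the choroid plexus score, each library's length trend as a covariate, leaving out the 4 libraries with Ttr under 100 CPM, leaving out the 2 libraries with the most negative length trend, and the exact permutation of list scores. Also chosen after, for the genes and the GABA members over both times alone, were the astrocyte score, the microglia score, the mitochondrial percent and the GC trend of each library as a covariate, each in turn. DESeq2 gives no adjusted p to genes removed by its independent filtering or as count outliers, and these were not counted as called. GC content and length came from a GRCm38 annotation and were known for 99.5% of the genes tested.

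The procedure was tested on simulated counts for the 17055 genes with sets of changed genes. At folds of 1.25, 1.5, 2 and 3 the edgeR test recovered 28%, 66%, 82% and 86% of 50 changed genes each in the comparison at 1 h, with 8 false calls among 139. At 6 h it recovered 26%, 62%, 82% and 82%, with 5 false calls among 131. Over both times it recovered 48%, 84%, 90% and 88%, with 9 false calls among 164. With no change simulated, the edgeR test called 0 genes and camera 0 of 26 lists. Camera called a median of 5 to 8 lists when the real libraries were regrouped. An added GC trend was reduced from a Spearman rho of 0.515 to -0.00701 by the correction. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

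No pair of libraries of a group was a duplicate: the chi-square of their counts per degree of freedom was 3.67 to 56.3 over 24 pairs. Spearman correlations of log-CPM were 0.987 to 0.997 within groups. No library was left out of the main tests, and no column of the tables was left unmapped.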

Results

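The data are read counts per gene from the hippocampus of wild-type C57BL/6 mice, an inbred laboratory strain. Each mouse received beta-sitosterol, a plant sterol close in structure to cholesterol, at 100 mg/kg by intraperitoneal injection, or vehicle. Tissue was taken 1 h or 6 h later, which makes 4 groups of 4 mice. The mice numbered 2 to 5 received vehicle and 6 to 9 beta-sitosterol in the 1 h groups. Mice 11 to 14 received vehicle and 17 to 20 beta-sitosterol in the 6 h groups. Counted reads per library ranged from 24815581 to 31266644, and 17055 genes were tested. Levels are given as CPM, the usual counts scaled to library size, with TMM scaling, as mean ± SD over mice.

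Transcripts of the choroid plexus, the epithelium that secretes cerebrospinal fluid and lies against the hippocampus, differed widely between mice of the same group. Ttr, which codes for the thyroid hormone carrier transthyretin made by that epithelium (chromosome 18, ENSMUSG00000061808), ranged from 45.8 to 6136 CPM over the 16 libraries. It lay under 100 CPM in 4 libraries, those of vehicle 1 h mouse 5, vehicle 6 h mouse 14 and beta-sitosterol 6 h mice 17 and 19. The mean log-CPM of 16 choroid plexus markers followed the first principal component of all genes, which held 32.6% of the variance (Pearson r = 0.977, Spearman rho = 0.959, n = 16). The permutation p was 1e-05 for both, the smallest that 100000 permutations give, and 5e-05 after Benjamini-Hochberg adjustment over 5 relations of this kind. Without the 2 mice farthest from the median score r was 0.977. The marker score differed by -0.457 log2 units between beta-sitosterol and vehicle over both times, within the spread between mice (two-sided exact permutation p = 0.596, 8 mice per arm). At 6 h all 16 markers had a negative log2 fold change with beta-sitosterol (median -0.61, camera adjusted p = 0.0324, and adjusted p = 0.796 with an estimated correlation). The camera adjusted p there was 0.0521 without mouse 9, 0.287 without mouse 11, 0.26 without mouse 12, 0.0999 without mouse 13, 0.442 without mouse 17 and 0.234 without mouse 19. Ttr itself was called in none of the 6 comparisons by the edgeR quasi-likelihood test.

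**Figure D1:**
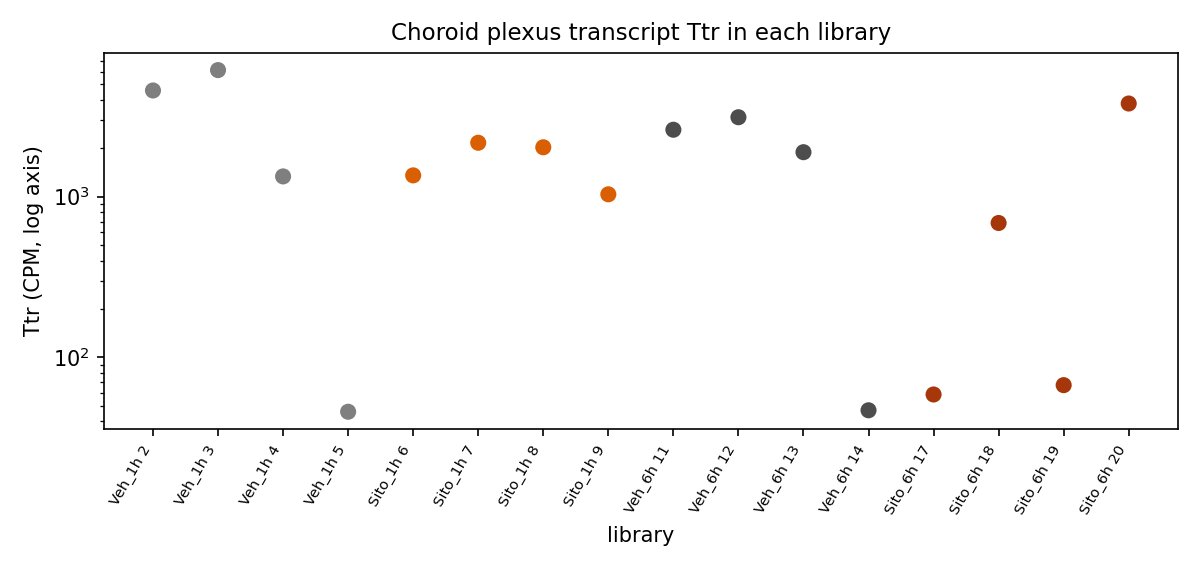
Ttr level of each of the 16 libraries in CPM on a log axis, by group, with a point for each mouse. Levels run from 45.8 to 6136 CPM, and the 4 libraries under 100 CPM belong to 3 of the 4 groups.

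The comparison of beta-sitosterol with vehicle at 1 h addresses the early response of the hippocampus to the sterol. Of 40 genes induced by neuronal activity, the immediate-early genes, 9 were lower in treated mice over the list alone, while the score of the whole list did not pass (two-sided exact permutation p = 0.0857, adjusted p = 0.464). Arc, which codes for a postsynaptic protein that regulates AMPA receptor trafficking (chromosome 15, 74669083 to 74672570, GRCm38), averaged 123.5 ± 16.7 CPM against 223 ± 50.7 CPM with vehicle (SD, n = 4 each), 1.81-fold lower (log2 fold change -0.85, SE 0.190). Fos, a subunit of the transcription factor AP-1 (chromosome 12, 85473890 to 85477273), averaged 10.4 ± 1.42 against 17.6 ± 4.29 CPM, 1.69-fold lower (SE 0.208 on the log2 scale). Npas4, a neuronal activity-dependent transcription factor, averaged 6.51 ± 0.697 against 9.79 ± 1.68 CPM (log2 fold change -0.59, SE 0.197). For each of these 3 genes every treated mouse lay below every vehicle mouse at 1 h, whereas Egr1, another gene of this kind, had a log2 fold change of -0.039 (SE 0.169). The 9 lower and 1 higher passed by the edgeR quasi-likelihood test, Benjamini-Hochberg adjusted over the list alone, and none passed over all genes tested. The lower ones were Arc, Fos, Npas4, Dusp1, Btg2, Nr4a1, Sik1, Ccn1 and Ier2, and the higher one was Homer1, a postsynaptic scaffold gene (1.19-fold). The list was lower by camera (median log2 fold change -0.045, 29 of 40 members negative, camera adjusted p = 0.00449, and adjusted p = 0.581 with an estimated correlation). That median was -0.11 without mouse 2, -0.085 without mouse 6, -0.074 without mouse 9, -0.069 without mouse 4 and -0.027 without mouse 5. It was -0.072 with the length trend as covariate, -0.029 after the GC and length correction, -0.030 after it with the choroid plexus score and -0.028 without the libraries low in Ttr. The choroid plexus score and the immediate-early score, both centred on group means, had r = -0.633 (permutation p = 0.00824, adjusted p = 0.0206, n = 16) and rho = -0.553 (permutation p = 0.0281, adjusted p = 0.0702), and r was -0.426 without the 2 farthest mice. The 10 immediate-early calls became 3 without vehicle 1 h mouse 3, 6 without beta-sitosterol 1 h mouse 9 and 4 without both. Without vehicle 1 h mouse 5 the camera adjusted p was 0.166, and without the 4 libraries low in Ttr it was 0.18.

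**Figure D2:**
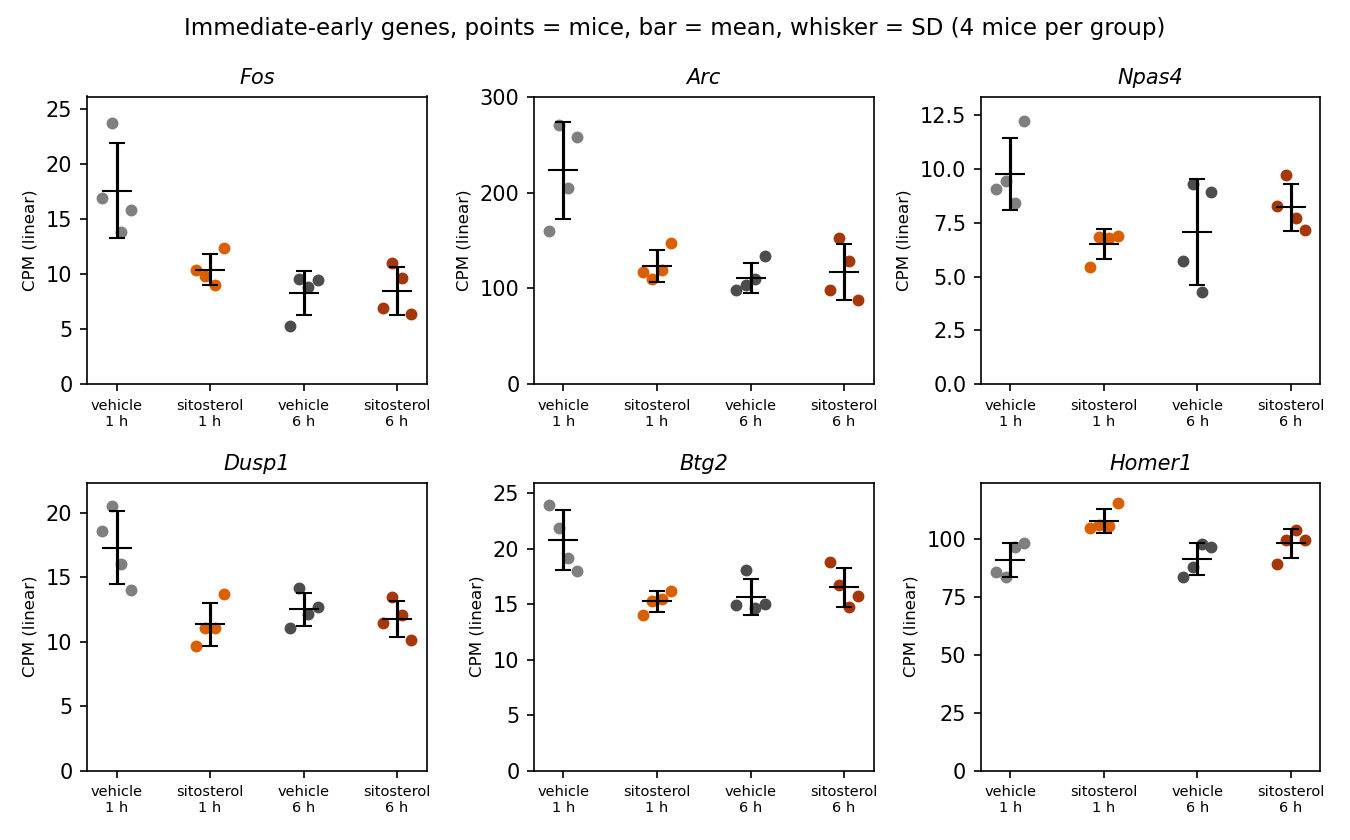
CPM of Fos, Arc, Npas4, Dusp1, Btg2 and Homer1 in each mouse of the 4 groups, with the group mean and SD (n = 4). At 1 h Arc averages 223 CPM with vehicle and 123.5 CPM with beta-sitosterol, and at 6 h 111 and 117 CPM.

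Astrocyte markers were lower at 1 h in 7 of 8 genes adjusted over the list alone by the edgeR quasi-likelihood test, and in none over all genes tested. They included Sox9, a glial transcription factor (1.31-fold, SE 0.147), Aldh1l1, a folate enzyme of astrocytes (1.18-fold, SE 0.0799), Aldoc, an astrocytic aldolase (1.14-fold), and Gja1, the gap junction gene of astrocytes (1.13-fold). The camera adjusted p was 5.42e-06, and the adjusted p = 0.304 with an estimated correlation. The list score gave an exact permutation p of 0.0286, the smallest that 4 mice against 4 allow, and 0.371 after adjustment. The 7 calls fell to 0 without vehicle 1 h mouse 3 or 4 or beta-sitosterol 1 h mouse 7 or 8, and to 1 without beta-sitosterol 1 h mouse 6. The median log2 fold change of these 7 genes, -0.18 (SE 0.0784), ran from -0.16 to -0.24 with each 1 h mouse left out in turn.

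Genes of GABA signalling were higher at 1 h in 6 of 21 members and lower in 1 by the edgeR quasi-likelihood test adjusted over the list alone, and none passed over all genes tested. Among the higher were Gad1, which codes for a GABA-synthesizing enzyme (1.17-fold, SE 0.0799), the receptor subunit genes Gabrb2 (1.11-fold) and Gabra2 (1.11-fold), and Gphn, the anchor of inhibitory synapses (1.12-fold). Lower was Slc6a11, a GABA transporter of astrocytes (1.23-fold, SE 0.0652). The camera adjusted p was 0.00224, and the adjusted p = 0.512 with an estimated correlation. The 7 calls became 1 under RLE scaling, without a count filter, with the strict filter, with a fit to the 1 h groups alone, after a GC and length correction with or without the choroid plexus score, with the length trend as covariate and without 1 h mice 3 and 9. They also became 1 when any of mice 2, 3, 4, 7, 8, 9, 12, 14, 17, 18, 19 or 20 was left out. The median log2 fold change of the list, 0.12, ran from 0.080 to 0.14 over the 28 settings run.

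Of 24 genes of cholesterol synthesis and uptake, 21 had a negative log2 fold change at 1 h with a median of -0.04. The list was lower by camera with an adjusted p of 0.00401, with an adjusted p = 0.557 with an estimated correlation, and with 0.0906 by camera without vehicle 1 h mouse 3. Transcripts of the mitochondrial genome had a median log2 fold change of -0.20 with 12 of 13 members negative, and those of microglia -0.13 with 9 of 9 negative, with camera adjusted p of 0.00022 and 0.00224, and adjusted p = 0.557 and 0.549 with an estimated correlation.

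Over all 17055 genes, 0 were called at 1 h by the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, with a smallest adjusted p of 0.251. An unadjusted p under 0.05 was found for 1742 genes, where 853 would arise by chance. DESeq2, which gave 12234 genes no adjusted p, called 54 genes, 33 higher and 21 lower, and limma called 0. The genes with the smallest p, which did not pass, were lower for Apold1, an early response gene of endothelial cells (2.16-fold, SE 0.199), Itih3 (1.30-fold), Hhex (1.83-fold), Dusp1, a phosphatase of MAP kinases (1.53-fold), and Map3k1 (1.29-fold). They were higher for Psmd11 (1.15-fold), Usp15 (1.14-fold), Nkrf (1.19-fold), Pcdhb13 (1.37-fold) and Arhgef3 (1.18-fold). Pcdhb13 belongs to a family of near-identical genes that can share reads, Dusp1 overlaps exons on the opposite strand, Arhgef3 on the same strand, and Usp15 on both. Without the 4 libraries low in Ttr, 13 genes were called, all lower.

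The comparison at 6 h addresses the later response. Of 23 genes of the liver X receptor and sterol transport group, 4 were lower in treated mice over the list alone, while the score of the whole list did not pass (two-sided exact permutation p = 0.0571, adjusted p = 0.66). Srebf1, a transcription factor of lipid synthesis, averaged 57.7 ± 5.53 against 72.1 ± 4.04 CPM (SD, n = 4 each), a log2 fold change of -0.32 (SE 0.0754). Abca7, a lipid transporter, averaged 20.6 ± 0.779 against 26.3 ± 1.44 CPM, 1.28-fold lower, and Apoe, the main lipid-carrying protein of the brain, 1041 ± 75.1 against 1254 ± 49.7 CPM, 1.20-fold lower (SE 0.0656). With Nr1h2, which codes for liver X receptor beta (1.14-fold), these were the 4 members lower by the edgeR quasi-likelihood test adjusted over the list alone, and none passed over all genes tested. Abca1, another target of this receptor, had a log2 fold change of -0.11 (SE 0.0730) and an edgeR adjusted p of 0.549. The list was lower by camera (median -0.09, 18 of 23 members negative, adjusted p = 0.00528, and adjusted p = 0.382 with an estimated correlation). The 4 calls became 0 after the GC and length correction, with or without the choroid plexus score, and 0 without the libraries low in Ttr, and 7 without beta-sitosterol 6 h mouse 20. The median log2 fold change of these 4 genes went from -0.30 (SE 0.0705) to -0.19 (SE 0.0664) after that correction, and the median of the list was -0.12 without the libraries low in Ttr. At 6 h the microglia score differed by -0.13 log2 units (exact permutation p = 0.0571, adjusted p = 0.66) and the mitochondrial share of the reads by -0.487 percentage points (exact permutation p = 0.114, adjusted p = 0.179). Both lists were lower by camera (adjusted p = 0.00818 for microglia markers and 0.0078 for mitochondrial transcripts, and adjusted p = 0.651 for each with an estimated correlation). The first was 0.0852 without mouse 14 and 0.0942 without mouse 20, and the second 0.0752 without mouse 11 and 0.0714 without mouse 18.

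GABA genes were again higher by camera at 6 h (median 0.11, 15 of 21 members positive, camera adjusted p = 0.00528, and adjusted p = 0.651 with an estimated correlation), with no member passing over the list alone. Oligodendrocyte markers had a median log2 fold change of -0.25 with all 10 negative (camera adjusted p = 0.00528, and adjusted p = 0.651 with an estimated correlation). Kpna1 and Kpna4, which code for importin alpha proteins of nuclear import, were higher adjusted over a list of 18 genes alone by the edgeR quasi-likelihood test (1.10-fold, SE 0.0422, and 1.12-fold, SE 0.0468). Igf1, a growth factor, averaged 9.79 ± 0.939 against 7.33 ± 0.762 CPM (SD, n = 4 each), 1.34-fold higher, and was the only one of 14 estrogen-related genes to pass over that list alone by the edgeR test. Fkbp5, a glucocorticoid-induced chaperone partner, had a log2 fold change of 0.40 (SE 0.152) and an edgeR adjusted p of 0.353, or 0.23 (SE 0.127) without mouse 19, and Fos and Arc had 0.041 (SE 0.217) and 0.070 (SE 0.190).

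At 6 h 0 genes were called by the edgeR quasi-likelihood test, Benjamini-Hochberg adjusted, with a smallest adjusted p of 0.321. An unadjusted p under 0.05 was found for 2070 genes. DESeq2, which gave 12895 genes no adjusted p, called 123, 102 higher and 21 lower, and limma called 0. The genes with the smallest p, which did not pass, were lower for Ppp1r16a (1.16-fold), Plxnb1, a semaphorin receptor (1.20-fold), Hrh1, a histamine receptor (1.41-fold), Rapgef3, an exchange factor activated by cyclic AMP (1.22-fold), and Adgrg1, an adhesion receptor (1.16-fold). They were higher for Atrnl1 (1.15-fold), Zfp644 (1.13-fold), Crispld1 (1.39-fold), the transcription factor Atf2 (1.13-fold) and Igf1. Exons of Plxnb1, Rapgef3 and Crispld1 overlap genes on the opposite strand, and those of Zfp644 and Atf2 genes on the same strand. With the length trend as covariate 2 genes were called, both lower.

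Averaging the effects at 1 h and 6 h uses 8 mice per arm and tests the mean effect, which a change at 1 time alone can also move. By the edgeR quasi-likelihood test, Benjamini-Hochberg adjusted, 13 genes passed, 1 higher and 12 lower. Itih3, a heavy chain of the inter-alpha-trypsin inhibitor family (chromosome 14, 30908572 to 30923760, GRCm38), fell from 26.9 ± 2.89 to 20.6 ± 0.893 CPM at 1 h and from 25.0 ± 0.763 to 20.6 ± 1.36 CPM at 6 h (SD, n = 4 each), 1.26-fold over both times (SE 0.0492, edgeR adjusted p = 0.0229). Plxnb1 (chromosome 9, 109095389 to 109119917) fell 1.20-fold (SE 0.0394, edgeR adjusted p = 0.0229), and Slc8b1, the sodium and calcium exchanger of mitochondria (chromosome 5, 120511168 to 120534024), 1.31-fold (SE 0.0683, edgeR adjusted p = 0.0365). Usp15, a deubiquitinating enzyme (chromosome 10, 123105006 to 123196995), rose 1.13-fold (SE 0.0311, edgeR adjusted p = 0.0382). For these 4 genes all treated mice lay on the same side of all vehicle mice at both times. Lower as well were Slc25a18, a mitochondrial glutamate carrier (1.22-fold), Caskin2 (1.21-fold), Fads2, a fatty acid desaturase (1.17-fold), Tril, a Toll-like receptor partner of astrocytes (1.16-fold), the phospholipase gene Plcb3 (1.16-fold), Pitpnm1, a phosphatidylinositol transfer protein (1.16-fold), Adgrg1 (1.14-fold), Ppp1r16a (1.14-fold) and Llgl1, a cell polarity gene (1.12-fold). Exons of Usp15, Plxnb1, Slc25a18, Caskin2, Tril and Plcb3 overlap genes on the opposite strand. An unadjusted p under 0.05 was found for 3492 genes. RLE scaling gave 117 calls, 75 higher and 42 lower, DESeq2 1307 (985 higher, 322 lower, 12 of the 13 shared, 8266 genes with no adjusted p) and limma 166 (117 higher, 49 lower, all 13 shared). The strict filter gave 497 (302 higher, 195 lower), the choroid plexus score 455 (255 higher, 200 lower), the length trend 210 (85 higher, 125 lower) and no count filter 96 (42 higher, 54 lower), while 0 passed without the libraries low in Ttr and 5, all lower, without mice 3 and 9. After the GC and length correction 2 genes were called, of which 1 was shared, and 3487 had an unadjusted p under 0.05; with the choroid plexus score added, 2 were called as well. The astrocyte score, the microglia score or the mitochondrial percent as a covariate gave 0 calls, and the GC trend of each library 1647 (1207 higher, 440 lower). The 13 calls became 0 without mouse 4, 7, 8, 11, 14 or 20, 1 without mouse 3, 2 without mouse 19, 5 without mouse 2, 25 without mouse 12, 39 without mouse 9, 61 without mouse 17, 285 without mouse 6 and 1206 without mouse 5.

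GABA genes were higher over both times in 8 of 21 members and lower in 1 by the edgeR quasi-likelihood test adjusted over the list alone, with none over all genes tested. Among the higher, Gphn was 1.12-fold higher (SE 0.0421), Gad1 1.12-fold, Gabbr2 1.12-fold, Gabra2 1.11-fold and Gabrb2 1.11-fold, and Slc6a11 was 1.16-fold lower (SE 0.0461). The list was higher by camera (median 0.10, adjusted p = 0.000804, and adjusted p = 0.363 with an estimated correlation). Its score gave an exact permutation p of 0.00653, and 0.0601 after adjustment over the lists. The 9 calls became 0 with the astrocyte score or the mitochondrial percent as covariate (list median 0.061 and 0.052) and 2 with the microglia score.

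Of the sterol transport group, 6 of 23 members were lower and 2 higher over both times by the edgeR quasi-likelihood test adjusted over the list alone, with none over all genes tested. Lower were Apoe (1.18-fold, SE 0.0464), Srebf1 (1.18-fold), Abca7 (1.20-fold), Cyp27a1, a sterol hydroxylase (1.24-fold), the desaturase gene Scd1 (1.18-fold) and Nr1h2 (1.11-fold). Higher were the lipoprotein lipase gene Lpl (1.16-fold) and Cyp7b1, an oxysterol hydroxylase (1.10-fold). The camera adjusted p was 0.00501, and the adjusted p = 0.363 with an estimated correlation. The 8 calls became 5 without vehicle 6 h mouse 11, 5 with the length trend as covariate and 5 without mice 3 and 9.

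**Figure D3:**
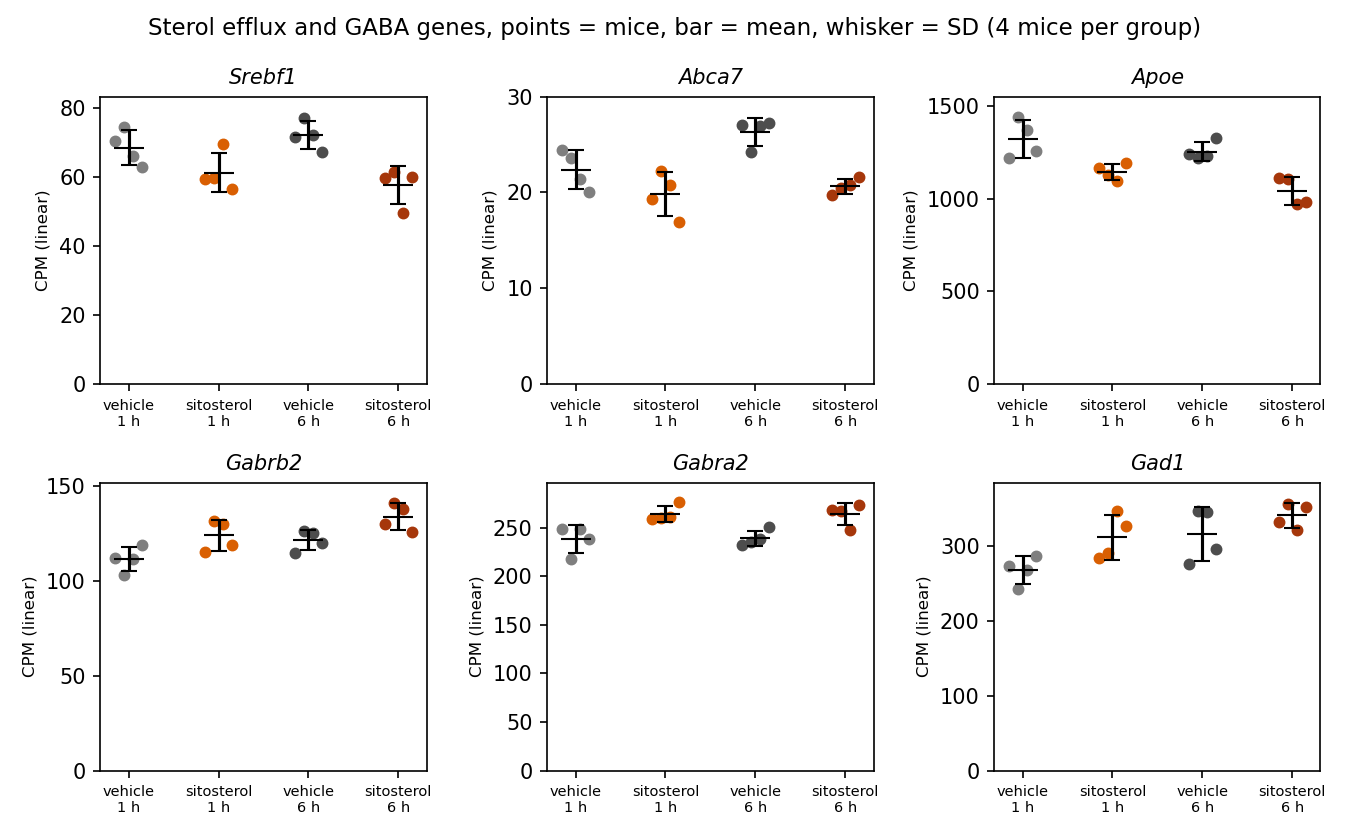
CPM of Srebf1, Abca7, Apoe, Gabrb2, Gabra2 and Gad1 in each mouse of the 4 groups, with the group mean and SD (n = 4). Apoe averages 1254 CPM with vehicle and 1041 CPM with beta-sitosterol at 6 h.

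Importin and sphingosine pathway genes were higher in 5 of 18 members (Kpna1, Kpna3, Kpna4, Kpna6 and Kpnb1, at up to 1.10-fold) and lower in 2 over both times adjusted over the list alone by the edgeR quasi-likelihood test. The lower ones were Sgpl1, a sphingosine 1-phosphate lyase (1.07-fold), and the receptor gene S1pr1 (1.08-fold), and camera did not call the list (adjusted p = 0.104). The 7 calls became 2 without mouse 3, 11 or 14, 4 without mouse 19, and 4 with the length trend or with the GC and length correction and choroid plexus score. They were also 4 without the libraries low in Ttr. Chaperone genes were higher in 5 of 26 members of the proteostasis list by the same measure (Hsph1 at 1.14-fold, SE 0.0452, Hsp90aa1 at 1.12-fold, Hsp90ab1 at 1.11-fold, Hspd1 and Hspa8), with a camera adjusted p of 0.00749, and adjusted p = 0.573 with an estimated correlation. Those 5 became 3 without mouse 9, 14 or 18, and 3 without mice 3 and 9.

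Astrocyte markers were lower over both times in 6 of 8 genes adjusted over the list alone by the edgeR quasi-likelihood test (Sox9 1.24-fold, Aldoc 1.11-fold and Gja1 1.10-fold among them), with a camera adjusted p of 0.000473, and adjusted p = 0.363 with an estimated correlation. These 6 calls became 0 without mouse 8, 11 or 20, 2 without mouse 4 or 14, 3 without mouse 18, 0 with the length trend as covariate and 3 without mice 3 and 9. Mitochondrial transcripts were lower in 9 of 13 genes by the same measure at a median log2 fold change of -0.18, with a camera adjusted p of 0.000473, and adjusted p = 0.573 with an estimated correlation. The log2 fold changes over both times had a Spearman correlation of -0.200 with transcript GC content and 0.141 with transcript length across genes, which are not independent replicates. The mitochondrial share of the reads was lower with beta-sitosterol over both times by a difference of -0.623 percentage points (two-sided exact permutation p = 0.0106, 8 mice per arm), and the trend of expression on GC content by -0.178 (exact permutation p = 0.0184). Both had an adjusted p of 0.0459 over 5 measures of the libraries. The astrocyte score differed by -0.15 log2 units (exact permutation p = 0.00408, adjusted p = 0.0601 over 26 lists) and the microglia score by -0.13 (exact permutation p = 0.0106, adjusted p = 0.069).

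**Figure D4:**
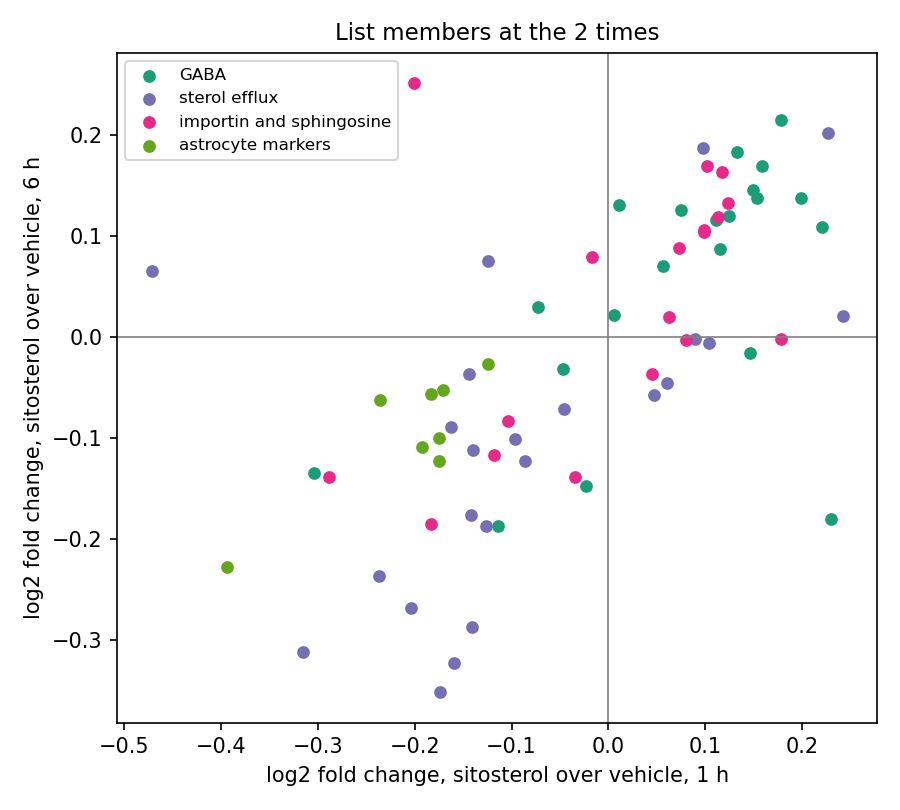
Log2 fold change of beta-sitosterol against vehicle at 1 h (x axis) and 6 h (y axis), a point for each member of the GABA, sterol transport, importin and astrocyte lists. The median over the 21 GABA members is 0.12 at 1 h and 0.11 at 6 h.

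The effects at 1 h and 6 h, which share no library, had a Pearson r of 0.307 across the 17055 genes and a Spearman rho of 0.453, with the same sign for 70.5% of genes. Permuting the treatment within each time gave permutation p = 0.07 for Pearson r and 0.01 for Spearman rho, the smallest that 100 draws allow. Pearson r was 0.0256 and rho 0.16 without a count filter, 0.565 and 0.65 for genes with a mean of at least 5 CPM, and 0.125 and 0.269 without 1 h mice 3 and 9. They were 0.191 and 0.347 with the choroid plexus score, and 0.175 and 0.338 with that score and the GC and length correction. Leaving out a mouse moved r by over 1.5 times only for vehicle 1 h mouse 2 (0.201).

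The difference of the effects at 6 h and 1 h tests whether the response changed with time. Immediate-early genes gave the smallest camera p, with a median of 0.09 and 26 of 40 members positive (camera adjusted p = 3.49e-05, and adjusted p = 0.711 with an estimated correlation). Arc had a log2 difference of 0.93 (SE 0.268), Npas4 of 0.81 (SE 0.279) and Fos of 0.80 (SE 0.300), each with an edgeR adjusted p of 1.00. Btg2, an antiproliferative early response gene, passed over the list alone (log2 difference 0.52, SE 0.136), and Gal, the neuropeptide galanin, over the estrogen-related list alone (-1.16, SE 0.341), both by the edgeR quasi-likelihood test. Over all genes 0 were called by the edgeR quasi-likelihood test, 0 by DESeq2 and 0 by limma, and 327 had an unadjusted p under 0.05, fewer than the 853 that arise by chance. The genes with the smallest p, none of which passed, had positive differences for Hhex (1.14), Apold1 (1.11), Hey2 (0.71), Btg2 and Etv6 (0.36), and negative ones for Olig2 (-0.53), Trib3 (-1.90), Col6a4 (-1.95), Gal and Ccdc121 (-1.10).

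In vehicle mice the 6 h group was compared with the 1 h group, which addresses time since the injection together with the hour of the day, since the labels do not separate these. Of 40 immediate-early genes 9 were lower at 6 h over the list alone, while the score of the whole list did not pass (two-sided exact permutation p = 0.0857, adjusted p = 0.433). Fos averaged 8.27 ± 2.00 against 17.6 ± 4.29 CPM (SD, n = 4 each), 2.13-fold lower (SE 0.211), Arc 111 ± 15.5 against 223 ± 50.7 CPM, 2.01-fold lower (SE 0.191), and Egr2, a zinc finger transcription factor, was 3.14-fold lower (SE 0.340). The 9 passed by the edgeR quasi-likelihood test adjusted over the list alone, none was higher, and none passed over all genes tested. They became 14 after the GC and length correction and 15 after it with the choroid plexus score. The others of the 9 were Btg2, Nr4a1, Sik1, Dusp1, Ccn1 and Tiparp. The camera adjusted p was 0.00013, and the adjusted p = 0.491 with an estimated correlation, and camera gave 0.0575 without vehicle 6 h mouse 11. Microglia markers were lower in 5 of 9 genes over the list alone (P2ry12 1.26-fold, Cx3cr1 1.17-fold), with a camera adjusted p of 1.62e-05, and adjusted p = 0.405 with an estimated correlation. Astrocyte markers were lower in 4 of 8 (Aqp4, the water channel of astrocytes, 1.29-fold, SE 0.0694), with a camera adjusted p of 0.00013, and adjusted p = 0.405 with an estimated correlation. Red blood cell transcripts were lower in 3 of 5 (Alas2 1.57-fold), with a camera adjusted p of 0.00215, and adjusted p = 0.491 with an estimated correlation. This comparison shares the vehicle 1 h libraries with the treatment comparison at 1 h, so the immediate-early lists of the comparisons are not independent of each other.

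Over all genes 0 were called between the times in vehicle mice by the edgeR quasi-likelihood test, with a smallest Benjamini-Hochberg adjusted p of 0.137 and 1808 genes at an unadjusted p under 0.05. DESeq2, which gave 3640 genes no adjusted p, called 94, 21 higher and 73 lower, and limma 0. The genes with the smallest p, which did not pass, were lower for Apold1 (2.22-fold), Gpam (1.22-fold), Mob1a (1.26-fold), Tiparp (1.35-fold) and Aqp4, and higher for Sulf2 (1.27-fold), Pcyox1l (1.20-fold), Elfn1 (1.23-fold), the proline transporter gene Slc6a7 (1.23-fold) and Sp9 (1.58-fold). The count was 9 without a count filter, 2 with the choroid plexus score, 12 with that score and the GC and length correction, and 7 without the libraries low in Ttr. It was 2 without vehicle 6 h mouse 11 and 7 without vehicle 1 h mouse 5.

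In beta-sitosterol mice, Plin4, a lipid droplet protein induced by glucocorticoids, averaged 30.6 ± 23.4 CPM at 6 h against 6.37 ± 0.876 CPM at 1 h (SD, n = 4 each), 4.81-fold higher (log2 fold change 2.27, SE 0.444), with 64.8 CPM in mouse 19 and a log2 fold change of 1.59 (SE 0.269) without it. In vehicle mice it averaged 20.6 ± 3.38 CPM at 6 h against 5.99 ± 2.11 CPM at 1 h, 3.44-fold higher (SE 0.447), and with Sult1a1 (1.43-fold) it passed there too over the list alone by the edgeR test. The difference between the treated and vehicle changes was 0.48 on the log2 scale (SE 0.624, edgeR adjusted p = 1.00). Of 26 glucocorticoid-responsive genes 3 were higher by the edgeR quasi-likelihood test adjusted over the list alone, namely Plin4, Sult1a1 (1.56-fold, SE 0.159) and Lcn2, and none over all genes tested. The acute-phase gene Lcn2 was at 28.4 CPM in mouse 19 at 6 h against 1.53 to 1.94 CPM in the other mice of that group, and its log2 fold change of 4.98 (SE 1.19) was 2.71 (SE 0.535) without that mouse. The list was higher by camera (median 0.11, adjusted p = 0.000217, and adjusted p = 0.578 with an estimated correlation), and its 3 calls became 5 without mouse 2 or 20, 6 without mouse 5 and 5 with DESeq2. The list median was 0.059 without mouse 19, with 3 calls and a camera adjusted p of 0.0237, and 0.070 with the choroid plexus score, with 2 calls. Microglia markers were lower in 2 of 9 genes over the list alone (P2ry12 1.28-fold, Cx3cr1 1.18-fold), with a camera adjusted p of 1.05e-05, and adjusted p = 0.578 with an estimated correlation. Immediate-early genes had none passing over the list alone, and their median log2 fold change was 0.02 and their mean -0.0074. Over all genes 0 were called by the edgeR quasi-likelihood test, with a smallest Benjamini-Hochberg adjusted p of 0.281 and 1189 genes at an unadjusted p under 0.05, while DESeq2 called 14, 7 higher and 7 lower, and limma 0. The genes with the smallest p, which did not pass, were higher for Lrg1, an acute-phase glycoprotein (3.70-fold), Tgm2 (1.39-fold), Rtp1 (3.35-fold), Plin4 and Prodh (1.29-fold), and lower for Cbfb (1.22-fold), Pcsk6 (1.23-fold), Gsap (1.36-fold), the endothelin receptor gene Ednrb (1.37-fold) and S1pr1 (1.21-fold). The count was 2 without the libraries low in Ttr and 1 without beta-sitosterol 6 h mouse 18.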

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

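The camera tests of the difference of the effects were fixed before the data were examined. Of the tests of explanations and splits in this part, those of a single library for the counts of immediate-early and GABA genes and the split of the genes at an unadjusted p under 0.05 over both times were chosen before their results were seen, and the others were chosen after. In 380 groups of 4 values, 16 held a mouse whose distance to the nearest of the others exceeded Dixon's critical share of the range of a group of that size, where chance gives about 19 (1 in 20).

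The vehicle 6 h mouse 11 had 5.32 CPM of Fos against 8.78 to 9.53 CPM in the others of its group (a gap of 0.857 of the range), and 29.4 CPM of Nkrf against 32.0 to 32.6 CPM (0.831). In beta-sitosterol 6 h mice, mouse 17 had 31.9 CPM of Nkrf against 34.7 to 35.1 CPM (0.885), and mouse 20 had 88.3 CPM of Per1 against 97.9 to 98.5 CPM (0.949) and 23.2 CPM of Caskin2 against 26.8 to 27.3 CPM (0.89). The beta-sitosterol 1 h mouse 6 had 5.46 CPM of Npas4 against 6.82 to 6.89 CPM (0.957) and 5.57 CPM of Slc8b1 against 6.54 to 6.65 CPM (0.907). Tsc22d3 was at 64.4 CPM in vehicle 1 h mouse 2 against 94.1 to 100.7 CPM (0.849), Adgrg1 at 75.4 CPM in vehicle 1 h mouse 5 against 82.1 to 83.4 CPM (0.847), and Btg2 at 18.1 CPM in vehicle 6 h mouse 12 against 14.6 to 15.1 CPM (0.862). Ttr was at 46.8 CPM in vehicle 6 h mouse 14 against 1892 to 3122 CPM (0.88). The sterol efflux score of vehicle 1 h mouse 3 was 5.34 against 5.21 to 5.22 log2 units (0.947). The beta-sitosterol 1 h mouse 9 stood apart in Plxnb1 (130.5 against 149.8 to 152.0 CPM, 0.906), in the inflammation score (1.98 against 2.09 to 2.11, 0.908), in depth (26269826 against 28161039 to 28360647 reads, 0.905) and in the trend of expression on transcript length (-0.26 against 0.09 to 0.14, 0.874).

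Between 1 h and 6 h, camera gave a difference of the beta-sitosterol effects for 7 lists, and none passed with an estimated correlation. The adjusted p was 3.49e-05 for immediate-early genes (median log2 fold change -0.05 at 1 h and 0.04 at 6 h), 0.00498 for meningeal and mural markers (-0.09 and 0.10), 0.00498 for oligodendrocyte markers (-0.014 and -0.25) and 0.00589 for astrocyte markers (-0.18 and -0.08). It was 0.0143 for thalamic markers (-0.30 and 0.04), 0.0337 for choroid plexus markers (-0.69 and -0.61) and 0.0339 for cholesterol synthesis genes (-0.04 and -0.011). For choroid plexus markers the median and mean of the difference were 0.11, while camera gave the lower direction. Their log-CPM score differed by 0.099 at 1 h and -1.01 at 6 h.

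After the GC and length correction the lower immediate-early genes at 1 h kept 96.4% of their median log2 fold change. It went from -0.59 (median SE 0.148) to -0.57 (SE 0.149), which argues against these trends as the whole cause. With the choroid plexus score in the fit these genes kept 97.4%. That score differed by only 0.099 log2 units at 1 h, so its fit could remove little. With each of the 8 mice left out in turn these immediate-early genes kept at least 87.5% (-0.52, SE 0.161, without vehicle 1 h mouse 5). They were picked by their p over all these mice, which limits what 1 mouse can take away, so this does not decide on a single library. Of the count, 3 lower members were called without vehicle 1 h mouse 3, whose library also has a negative length trend, which lies between the bounds set for and against a single library (the 5 without beta-sitosterol 1 h mouse 9 met the bound against), so for the count that mouse cannot be told apart from the treatment. Of the 35 splits of these 8 mice 1, the real one with 10, gave as many calls over this list (highest other 2), but the list was picked after its count was seen, and 2 of 35 gave as many in any of the 26 lists (highest other 12), so chance is not excluded. An effect of beta-sitosterol stays open as a hypothesis.

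Over both times, the GABA members called higher were at least 5 whichever mouse was left out (5 without vehicle 6 h mouse 11, beta-sitosterol 6 h mouse 18 or beta-sitosterol 1 h mouse 8, from 8 with all mice), and their median log2 fold change kept 90.8% after the GC and length correction (from 0.15, median SE 0.0412, to 0.14, SE 0.0426), which argues against these as whole causes. The 12 genes called lower kept 91.3% of their median after the correction (from -0.22, SE 0.0386, to -0.20, SE 0.0409), which argues against these trends as the whole cause of the size. They kept at least 95.3% with a mouse left out. They were picked by their p over all these mice, which limits what 1 mouse can take away, so this does not decide on a single library. The calls went from 13 to 2 after the correction (12 of the 13 fold changes smaller, 11 standard errors larger, 1 gene still called). They went to 0 without mouse 4, 7, 8, 11, 14 or 20. Measures that differ between treatments left the GABA members 58.0% with the astrocyte score in the fit (0.089, SE 0.0571), 82.7% with the microglia score (0.13, SE 0.0538), 53.8% with the mitochondrial percent (0.082, SE 0.0418) and 135% with the GC trend, and the 12 genes 79.0%, 79.4%, 85.3% and 109%. The GC trend took nothing away, but moves with treatment too, so this decides nothing. The first 3 left 0 genes called by edgeR (832, 2256 and 1822 at an unadjusted p under 0.05, against 853 expected on average without any change). They move with the treatment and the 12 genes were picked by their p, so these 3 cannot be told apart from it. A treatment effect of small size is a hypothesis that stays open beside a change of glial or mitochondrial share.

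The choroid plexus markers moved together over the 16 libraries, with a median r of 0.993 between a marker and the mean of the others (lowest 0.775, Tmem72). Their score ranged over 1.19 to 4.81 log2 units within groups, more than the difference of -0.457 between treatments. This is consistent with varying amounts of choroid plexus carried along at dissection. Of the variance of the score 88.3% lay within groups, which argues against treatment or time as the whole cause, although a random grouping would also leave most of it there. With an exact permutation p of 0.596 a smaller effect of the treatment stays open.

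Over both times the real grouping, 1 of the 100 draws, gave the most called genes (13, highest other 0). It also gave the most genes at an unadjusted p under 0.05 (3492, highest other 2333). This argues against chance without excluding it. For the 9 GABA members, a list picked after its count was seen, 1 draw gave as many in that list (highest other 1) and 4 in any list (highest other 15), while the exact permutation p of the list score was 0.0601 after adjustment, so chance stays open. The 8 sterol efflux members (1 draw, highest other 2) and 7 importin members (1 draw, highest other 2) were picked after their counts were seen, and 6 and 9 draws gave as many in any list, so chance is not excluded for them. The same holds for the 7 astrocyte members at 1 h (1 of 35, highest other 5, and 8 of 35 in any list) and the 4 sterol efflux members at 6 h (1 of 35, highest other 1, and 4 of 35 in any list). The 9 immediate-early members lower between times with vehicle were matched by 2 of 35 splits (highest other 9).

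A count of 0 is matched by every split and so decides nothing, which holds for all 35 splits at 1 h (highest other 622), at 6 h (highest other 0), between times with vehicle (highest other 920) and with beta-sitosterol (highest other 0), and for all 100 draws of the difference of the effects (highest other 1). The 622 genes came from a split of vehicle mice 2, 3 and 4 and treated mouse 9 against the rest. The 920 came from one of vehicle mice 2, 3, 4 and 11. Mitochondrial reads were 4.86 to 6.04% in these mice and at most 4.57% in the rest, a link not tested. Each split is the real grouping with vehicle 1 h mouse 5 exchanged for 1 mouse of the other group. Neither is thus independent of the groups, and 2 and 3 of the other splits called any gene. For lists called by camera, the real count was 10 at 1 h (9 of 35 splits as large, highest other 13), 8 at 6 h (9 of 35, highest other 11), 8 over both times (27 of 100, highest other 12), 7 for the difference of the effects (49 of 100, highest other 12), 9 between times with vehicle (14 of 35, highest other 14) and 6 between times with beta-sitosterol (18 of 35, highest other 10). A count of camera calls is thus no evidence of a treatment effect here. For the effects at the 2 times, the Pearson r of 0.307 was reached by 7 of 100 draws (highest other 0.488) and the Spearman rho of 0.453 by 1, the real one (highest other 0.36), so the measures differ and chance stays open for the correlation.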

How the results depend on the processing

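The GC and length corrections, the length trend, the sets of libraries left out and the exact permutation of list scores were chosen after seeing the data, as were the 4 covariates named last among the counts over both times and the 11 pairs of a list and a comparison whose counts of members were recomputed. Genes and list members were recomputed under 28 settings besides the main one, 16 of which leave out a mouse (27 over both times and for the difference of the effects), and the genes and GABA members over both times under 4 more. The mice are vehicle 1 h 2 to 5, beta-sitosterol 1 h 6 to 9, vehicle 6 h 11 to 14 and beta-sitosterol 6 h 17 to 20. Of the values of named genes, 3066 kept their direction and side of the threshold, 56 came to pass it, 137 no longer passed and 75 turned in direction. Of the tests of the 48 pairs of a list and a comparison that camera called (by camera and up to 3 further tests), 1152 kept both, 259 no longer passed and 7 turned, all of choroid plexus markers. Of the 108 pairs not called, 47 gained a camera call under a setting (163 of 2879 tests), and none passed with an estimated correlation, fry or exact permutation. Of counts of called genes 127 stayed within 1.5 times and 43 did not, and of counts of list members 241 did and 66 did not. For the values below, the cause was not tested, except that some settings use fewer genes or libraries by construction. No paired analysis was possible because each animal number belongs to only 1 group. Depth sets a limit for genes with few reads, such as Lcn2 in 1 h mice, and small folds are limited by the spread between mice; of the smallest simulated changes 28% were recovered at 1 h.

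At 1 h the main count of called genes was 0 by the edgeR quasi-likelihood test (1742 at an unadjusted p under 0.05, limma 0), with 54 by DESeq2 and 13 without the libraries low in Ttr. At 6 h it was 0 (2070 at an unadjusted p under 0.05, limma 0), with 123 by DESeq2 and 2 with the length trend as covariate. Over both times it was 13, with 117 under RLE, 96 without a count filter, 497 with the strict filter, 455 with the choroid plexus score, 2 after the GC and length correction, 2 after that correction with the score, 210 with the length trend, 0 without the libraries low in Ttr, 5 without mice 3 and 9 (all 5 shared), 1307 by DESeq2 and 166 by limma, and with the astrocyte score, the microglia score or the mitochondrial percent as covariate 0, and with the GC trend 1647. Leaving out a mouse gave 0 (mouse 4, 7, 8, 11, 14 or 20) to 1206 (mouse 5). Between times with vehicle the main count was 0 (1808 at an unadjusted p under 0.05, limma 0), with 9 without a count filter, 2 with the choroid plexus score, 12 with that score and the GC and length correction, 7 without the libraries low in Ttr, 94 by DESeq2, and 0 to 7 with a mouse left out (2 without mouse 11, 7 without mouse 5). Between times with beta-sitosterol it was 0 (1189 at an unadjusted p under 0.05, limma 0), with 2 without the libraries low in Ttr, 14 by DESeq2, and 0 to 1 with a mouse left out (1 without mouse 18). The difference of the effects gave 0 genes under every setting run, by edgeR, DESeq2 and limma (327 at an unadjusted p under 0.05). The correlation of the effects, 0.307, was 0.0256 without a count filter and 0.565 with the strict filter.

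Counts of members adjusted over the list alone moved as follows. At 1 h the 10 immediate-early calls became 4 without mice 3 and 9 and 3 (without mouse 3) to 11 with a mouse left out, with 6 without mouse 9. The 7 astrocyte calls became 3 with the length trend, 2 without mice 3 and 9, 4 with the 1 h groups alone, and 0 (without mouse 3, 4, 7 or 8) to 7, with 1 without mouse 6. The 7 GABA calls became 1 under RLE, without a count filter, with the strict filter, after the GC and length correction, after it with the choroid plexus score, with the length trend, without mice 3 and 9 and with the 1 h groups alone. They were 1 (mouse 2, 3, 4, 7, 8, 9, 12, 14, 17, 18, 19 or 20) to 7 with a mouse left out. At 6 h the 4 sterol efflux calls became 0 after the GC and length correction, 0 after it with the score, 0 without the libraries low in Ttr, and 3 to 7 (without mouse 20). Over both times the 8 sterol efflux calls became 5 with the length trend, 5 without mice 3 and 9, and 5 (without mouse 11) to 12. The 7 importin calls became 4 after the correction with the score, 4 with the length trend, 4 without the libraries low in Ttr, and 2 (without mouse 3, 11 or 14) to 7, with 4 without mouse 19. The 6 astrocyte calls became 0 with the length trend, 3 without mice 3 and 9, and 0 (without mouse 8, 11 or 20) to 7, with 2 without mouse 4 or 14 and 3 without mouse 18. The 5 proteostasis calls became 3 without mice 3 and 9, and 3 (without mouse 9, 14 or 18) to 7. Between times the 9 immediate-early calls with vehicle became 14 after the GC and length correction and 15 after it with the score. The 3 glucocorticoid calls with beta-sitosterol became 5 by DESeq2, and 3 to 6 (without mouse 5), with 5 without mouse 2 or 20. The 9 GABA calls over both times became 0 with the astrocyte score, 2 with the microglia score and 0 with the mitochondrial percent, and moved by at most 1.5 times in the other settings run.

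No camera call held with an estimated correlation in any comparison. With an estimated correlation, the adjusted p of the list tests was immediate-early 0.581, cholesterol synthesis 0.557, sterol efflux 0.512, GABA 0.512, glutamate 0.618, endothelial 0.549, microglia 0.549, astrocyte 0.304, thalamus 0.618 and mitochondrial 0.557 at 1 h. Glucocorticoid 0.67, sterol efflux 0.382, choroid plexus 0.796 and 0.651 for the other lists called by camera resulted at 6 h. Glucocorticoid 0.574, sterol efflux 0.363, GABA 0.363, proteostasis 0.573, microglia 0.548, astrocyte 0.363, oligodendrocyte 0.573 and mitochondrial 0.573 resulted over both times. Immediate-early 0.711, cholesterol synthesis 0.921, choroid plexus 0.921, meninges and mural 0.711, astrocyte 0.711, oligodendrocyte 0.921 and thalamus 0.921 resulted for the difference. Immediate-early 0.491, glucocorticoid 0.729, cholesterol synthesis 0.563, GABA 0.491, glutamate 0.491, erythroid 0.491, microglia 0.405, astrocyte 0.405 and mitochondrial 0.491 resulted between times with vehicle. Choroid plexus 0.628 and 0.578 for the other lists called by camera resulted between times with beta-sitosterol. With fry, it was immediate-early 0.395, cholesterol synthesis 0.355, sterol efflux 0.181, GABA 0.181, glutamate 0.395, endothelial 0.331, microglia 0.331, astrocyte 0.0861, thalamus 0.523 and mitochondrial 0.331 at 1 h. Glucocorticoid 0.629, GABA 0.314, proteostasis 0.489, choroid plexus 0.654, microglia 0.473, oligodendrocyte 0.473 and mitochondrial 0.489 resulted at 6 h. Glucocorticoid 0.391, proteostasis 0.223, microglia 0.0787, oligodendrocyte 0.289 and mitochondrial 0.143 resulted over both times. Every list called by camera gave 0.996 for the difference. Immediate-early 0.281, glucocorticoid 0.615, cholesterol synthesis 0.336, GABA 0.281, glutamate 0.281, erythroid 0.281, microglia 0.124, astrocyte 0.124 and mitochondrial 0.281 resulted between times with vehicle. Glucocorticoid 0.615, GABA 0.584, choroid plexus 0.638, erythroid 0.584, microglia 0.285 and mitochondrial 0.584 resulted between times with beta-sitosterol. From exact permutation of the list scores, it was immediate-early 0.464, cholesterol synthesis 0.464, sterol efflux 0.464, GABA 0.371, glutamate 0.669, endothelial 0.464, microglia 0.464, astrocyte 0.371, thalamus 0.675 and mitochondrial 0.464 at 1 h. Glucocorticoid 0.743, choroid plexus 0.787 and 0.66 for the others resulted at 6 h. Glucocorticoid 0.391, sterol efflux 0.0601, GABA 0.0601, proteostasis 0.519, microglia 0.069, astrocyte 0.0601, oligodendrocyte 0.391 and mitochondrial 0.0976 resulted over both times. Every list called by camera gave 0.433 between times with vehicle and 0.557 with beta-sitosterol. With the strict filter it was glutamate 0.0841 and thalamus 0.0841 at 1 h. Glucocorticoid 0.191 and choroid plexus 0.0516 resulted at 6 h. Glucocorticoid 0.185 resulted over both times and 0.0695 between times with vehicle. With the choroid plexus score in the fit it was glucocorticoid 0.055 and choroid plexus 0.864 in the opposite direction at 6 h. Oligodendrocyte 0.0727 resulted over both times. Choroid plexus 0.963 in the opposite direction resulted for the difference. Choroid plexus 0.77 in the opposite direction and erythroid 0.0731 resulted between times with beta-sitosterol. After the GC and length correction it was microglia 0.0534 at 6 h. Mitochondrial 0.303 resulted between times with beta-sitosterol. With both of these together it was choroid plexus 0.674 at 6 h. Oligodendrocyte 0.0581 resulted over both times. Choroid plexus 0.999 resulted for the difference. Choroid plexus 0.867 in the opposite direction, erythroid 0.124 and mitochondrial 0.176 resulted between times with beta-sitosterol. With the length trend in the fit it was cholesterol synthesis 0.0731, glutamate 0.321, endothelial 0.0677 and thalamus 0.148 at 1 h. Glucocorticoid 0.266, choroid plexus 0.463, microglia 0.266, oligodendrocyte 0.0921 and mitochondrial 0.463 resulted at 6 h. Glucocorticoid 0.308, microglia 0.0663, oligodendrocyte 0.34 and mitochondrial 0.0755 resulted over both times. Choroid plexus 0.102 resulted for the difference. Glucocorticoid 0.0647 resulted between times with vehicle. Without the 4 libraries low in Ttr it was immediate-early 0.18 at 1 h. Choroid plexus 0.066 resulted at 6 h. Cholesterol synthesis 0.295, choroid plexus 0.0201 in the opposite direction and astrocyte 0.295 resulted for the difference. Choroid plexus 0.607 in the opposite direction and erythroid 0.0979 resulted between times with beta-sitosterol. Without the 2 libraries of most negative length trend it was sterol efflux 0.273 and thalamus 0.461 at 1 h. Oligodendrocyte 0.128 resulted over both times. Cholesterol synthesis 0.249 and thalamus 0.445 resulted for the difference. Cholesterol synthesis 0.144, GABA 0.159 and glutamate 0.144 resulted between times with vehicle.

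Camera calls lost at 1 h without 1 mouse were these. Immediate-early ran from 4.43e-05 to 0.166, with 0.166 without mouse 5. Cholesterol synthesis ran from 0.00054 to 0.0906, with 0.0906 without mouse 3. Sterol efflux ran from 0.00474 to 0.123, with 0.0906 without mouse 3, 0.0732 without mouse 6 and 0.123 without mouse 9. Glutamate ran from 0.00246 to 0.243, with 0.243 without mouse 3, 0.0686 without mouse 6, 0.0559 without mouse 7 and 0.0682 without mouse 8. Endothelial ran from 0.00298 to 0.0931, with 0.0931 without mouse 7. Thalamus ran from 0.00038 to 0.229, with 0.196 without mouse 2, 0.229 without mouse 3, 0.0795 without mouse 4, 0.153 without mouse 6, 0.0559 without mouse 7 and 0.11 without mouse 9. Camera calls lost at 6 h without 1 mouse were these. Glucocorticoid ran from 0.000115 to 0.354, with 0.0724 without mouse 11, 0.132 without mouse 12 and 0.354 without mouse 19. Proteostasis ran from 0.000261 to 0.0602, with 0.0602 without mouse 19. Choroid plexus ran from 5.53e-06 to 0.442, with 0.287 without mouse 11, 0.26 without mouse 12, 0.0999 without mouse 13, 0.442 without mouse 17, 0.234 without mouse 19 and 0.0521 without mouse 9. Microglia ran from 0.00319 to 0.0942, with 0.0852 without mouse 14 and 0.0942 without mouse 20. Mitochondrial ran from 0.000697 to 0.0752, with 0.0752 without mouse 11 and 0.0714 without mouse 18. Camera calls lost over both times without 1 mouse were these. Glucocorticoid ran from 0.000642 to 0.151, with 0.0771 without mouse 12, 0.122 without mouse 19 and 0.151 without mouse 2. Oligodendrocyte ran from 0.00362 to 0.144, with 0.0603 without mouse 11, 0.101 without mouse 12, 0.0662 without mouse 13, 0.113 without mouse 17, 0.055 without mouse 18, 0.062 without mouse 2, 0.144 without mouse 3, 0.0544 without mouse 4 and 0.126 without mouse 6. Camera calls lost for the difference without 1 mouse were these. Cholesterol synthesis ran from 0.00249 to 0.577, with 0.288 without mouse 12, 0.072 without mouse 13, 0.0926 without mouse 14, 0.0624 without mouse 18, 0.484 without mouse 19, 0.577 without mouse 3, 0.133 without mouse 6 and 0.208 without mouse 8. Choroid plexus ran from 2.09e-07 to 0.842, with 0.448 without mouse 11, 0.435 without mouse 12, 0.0813 without mouse 13, 0.621 without mouse 17, 0.416 without mouse 19, 0.0724 without mouse 4, 0.842 without mouse 5 in the opposite direction, 0.158 without mouse 7 and 0.0967 without mouse 8. Meninges and mural ran from 0.000557 to 0.116, with 0.0931 without mouse 17 and 0.116 without mouse 7. Astrocyte ran from 0.000184 to 0.149, with 0.0594 without mouse 13, 0.149 without mouse 19 and 0.0903 without mouse 3. Oligodendrocyte ran from 1.5e-07 to 0.223, with 0.223 without mouse 5 and 0.0678 without mouse 8. Thalamus ran from 6.91e-06 to 0.303, with 0.206 without mouse 19, 0.132 without mouse 2, 0.303 without mouse 3, 0.0959 without mouse 6 and 0.0678 without mouse 9. Camera calls lost between times with vehicle without 1 mouse were these. Immediate-early ran from 5.61e-07 to 0.0575, with 0.0575 without mouse 11. Glucocorticoid ran from 0.000388 to 0.518, with 0.251 without mouse 13, 0.115 without mouse 14 and 0.518 without mouse 2. Cholesterol synthesis ran from 0.000651 to 0.124, with 0.0535 without mouse 12 and 0.124 without mouse 3. GABA ran from 0.00938 to 0.15, with 0.118 without mouse 12 and 0.15 without mouse 3. Glutamate ran from 0.000189 to 0.124, with 0.124 without mouse 3. Camera calls lost between times with beta-sitosterol without 1 mouse were these. GABA ran from 0.00195 to 0.072, with 0.072 without mouse 6. Choroid plexus ran from 2.26e-08 to 0.0642, with 0.0642 without mouse 17. Erythroid ran from 0.000823 to 0.133, with 0.133 without mouse 6.

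Directions turned mostly for genes near no change. Without the 4 libraries low in Ttr, the log2 fold change was Egr1 0.078 at 1 h. Sgk1 0.25 resulted at 6 h. Fkbp5 -0.055 and Per1 -0.020 resulted for the difference. Sgk1 0.18, Tsc22d3 -0.033 and Ttr 0.45 resulted between times with beta-sitosterol. With the choroid plexus score in the fit it was Ttr 0.32 at 1 h. Sgk1 0.021 resulted at 6 h. Ttr 0.14 resulted over both times, -0.35 for the difference and 0.11 between times with vehicle. Tsc22d3 -0.040 resulted between times with beta-sitosterol. With the correction and the choroid plexus score together it was Ttr 0.31 at 1 h. Sgk1 0.0036 resulted at 6 h. Ttr 0.13 resulted over both times, -0.36 for the difference and 0.15 between times with vehicle. Sgk1 0.0028 and Tsc22d3 -0.038 resulted between times with beta-sitosterol. With the length trend in the fit it was Ttr 0.045 at 1 h. Ttr -0.32 resulted for the difference. With limma it was Ttr 0.46 at 1 h. Ttr -1.99 resulted for the difference. Tsc22d3 -0.016 resulted between times with beta-sitosterol. With RLE normalization it was Sgk1 0.0054 at 6 h. Without the low-count filter it was Sgk1 0.0072 at 6 h. With only the 2 groups compared it was Sgk1 0.0050 at 6 h. With DESeq2 it was Sgk1 0.0056 at 6 h. After the GC and length correction it was Per1 0.010 at 6 h. Without the 2 libraries of most negative length trend it was Per1 -0.026, Abca1 -0.055 and Ttr -0.63 for the difference. Arc 0.017 resulted between times with beta-sitosterol. With a mouse left out, ranges at 1 h were Egr1 -0.11 to 0.078 and Tsc22d3 -0.044 to 0.15. Ranges at 6 h were Fos -0.13 to 0.15, Arc -0.084 to 0.18, Sgk1 -0.20 to 0.16 and Tsc22d3 -0.11 to 0.15. Ranges over both times were Egr1 -0.015 to 0.13 and Tsc22d3 -0.011 to 0.12. Ranges for the difference were Fkbp5 -0.0094 to 0.24, Tsc22d3 -0.20 to 0.089, Per1 -0.022 to 0.11, Abca1 -0.052 to 0.076 and Ttr -1.95 to 0.55. Ranges between times with vehicle were Tsc22d3 -0.078 to 0.12. Ranges between times with beta-sitosterol were Arc -0.24 to 0.032, Sgk1 -0.25 to 0.12, Tsc22d3 -0.15 to 0.12 and Per1 -0.10 to 0.010.

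The median, mean and camera direction of a list differed in sign at 1 h for the monoamine, proteostasis and striatal lists, at 6 h for the circadian, monoamine and striatal lists, and over both times for the monoamine, inflammation, meninges and mural, and striatal lists. They differed for the difference of the effects for the estrogen, GABA, choroid plexus, microglia, CA pyramidal cell and sex-linked lists, with vehicle between times for the circadian, importin, proteostasis and sex-linked lists, and with beta-sitosterol between times for the immediate-early, importin, inflammation and sex-linked lists. Of these, camera called the choroid plexus list only.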

Other observations

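The tests in this part, apart from the exact permutations, were fixed as comparisons before the data were examined, and the genes singled out in it were chosen after their values were seen. Among 26 glutamate receptor and transporter genes, 5 were higher and 4 lower over both times by the edgeR quasi-likelihood test, Benjamini-Hochberg adjusted over the list alone, and none passed over all genes tested. The AMPA receptor subunit genes Gria1 (1.12-fold, SE 0.0543) and Gria3 (1.12-fold, SE 0.0405), the NMDA receptor subunit gene Grin2b (1.18-fold, SE 0.084), the metabotropic receptor gene Grm5 (1.10-fold) and the neuronal transporter gene Slc1a1 (1.13-fold) were higher with beta-sitosterol. The glial glutamate transporter genes Slc1a2 (1.10-fold) and Slc1a3 (1.09-fold), the metabotropic receptor gene Grm3 (1.11-fold) and the NMDA receptor subunit gene Grin2c (1.19-fold, SE 0.0778) were lower. Camera did not call the list (adjusted p = 0.0948). Over both times the astrocyte score differed by -0.15 log2 units (exact permutation p = 0.00408, adjusted p = 0.0601), the microglia score by -0.13 (exact permutation p = 0.0106, adjusted p = 0.069) and the mitochondrial share of the reads by -0.623 percentage points (exact permutation p = 0.0106, adjusted p = 0.0459). Neurod6 (1.17-fold) and Cpne4 (1.18-fold) among 9 markers of CA pyramidal cells and Stxbp6 (1.15-fold) among 7 of dentate granule cells were higher over their lists alone, while camera called neither list (adjusted p = 0.113 and 0.0815) and neither list score passed (exact permutation adjusted p = 0.391 for both). Rorb, an orphan nuclear receptor gene, was the only one of 20 clock genes to pass over that list alone over both times (1.20-fold lower, SE 0.0613).

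In the treated mice, inflammation-related genes differed between 1 h and 6 h in both directions over the list alone by the edgeR quasi-likelihood test. Socs3, a feedback inhibitor of cytokine signalling, was 1.86-fold higher at 6 h (SE 0.215) and Il4ra, an interleukin 4 receptor subunit, 1.48-fold (SE 0.160), while Gbp3, an interferon-induced guanylate-binding protein, was 1.41-fold lower (SE 0.162). At 1 h Socs3 was 1.70-fold lower with beta-sitosterol than with vehicle (SE 0.217), again over the list of 18 genes alone. No hypothesis was tested on these genes.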
